A study of Mus musculus with 3 samples.

How the data were processed

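The series holds 3 single-nucleus RNA libraries from mouse hippocampus, 1 from each of 3 female adult mice heterozygous for the D allele of Scn8a, a gene for a voltage-gated sodium channel alpha subunit. Their titles place them after seizure onset, and each mouse has a batch of its own (1, 2 and 3), so mouse and batch cannot be told apart. Per the labels' protocols, nuclei stained with propidium iodide were sorted, loaded on the 10x 3' platform with a target of 10000 nuclei and 60000 reads per nucleus, and sequenced on a NovaSeq. The same protocol text describes animals before onset and controls, which are not analysed here, and gives postnatal day 50 for animals it does not tie to these 3 mice. The age is therefore given only as adult.

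The deposited matrices hold raw UMI counts per gene and nucleus barcode, per the file headers made with Cell Ranger 7.0.0 for mice 1 and 2 and 7.1.0 for mouse 3, on mm10 per the submitters' processing notes. Whether intronic reads were counted is not given in the sources used here. Cell type labels were not used here, and classes were assigned from the counts. Gene positions come from an annotation of the same build. A point mutation cannot be read from 3' counts, so Scn8a counts hold both alleles together and do not check the genotype.

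Nuclei with at least 500 genes and at most 5% mitochondrial UMIs were kept, which removed 242, 703 and 1 nuclei of mice 1, 2 and 3 for low gene numbers and none for mitochondrial share. Scrublet, as implemented in scanpy 1.11.5, then called 732, 1444 and 265 doublets. Its automatic threshold called 0 in mouse 2, so there the expected rate of 0.8% per 1000 nuclei set the threshold, a choice made after that result was seen. Counts were scaled to 10000 UMIs and log-transformed for clustering only. It used 3000 variable genes without the members of the fixed lists, 30 principal components, 20 neighbours and Leiden clustering at resolution 1.5 (leidenalg 0.10.2). Clusters were named from fixed markers by their fold over the other nuclei of the same mouse, with at least 3 supporting markers at 2-fold. A cluster with such support still stayed unnamed where at least 2 markers of another class, and more than of its own, were among its 10 leading genes, which no cluster met, or where its median depth was under 1/3 of that of its mouse and none of its own markers was among the leading genes. A cluster without such support was named glutamatergic where at least 4 pan-glutamatergic markers were 2-fold higher than in inhibitory and glial nuclei of the same mouse, inhibitory markers were not raised and fewer than 2 ribosomal protein genes were among its 10 leading genes, and otherwise stayed unnamed. Of the unnamed nuclei of mouse 2, 3345 of 4837 lay in a cluster led by ribosomal protein genes, and of those of mouse 1, 277 of 300 in a shallow cluster. A granule, CA or mossy name with a mean marker log2 fold under 0.5 was replaced. It became subicular or cortical glutamatergic where that class had 3 supporting markers, and glutamatergic otherwise. An inhibitory subtype that led the next supported one by under 0.25 was named inhibitory. The markers were fixed before the data were examined, and the scoring rules were adjusted after the clusters were seen. Names are written with -like, since no other evidence of identity was available. Astrocyte marker Gpc5 was among the leading genes of CA1-like clusters with no CA1 marker among the first 10, which limits that name. The subicular or cortical glutamatergic name had no minimum mean fold. Its mean marker log2 fold went down to -0.06 in a cluster, which limits that name too.

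Raw counts were summed per mouse and class. Replicates are mice (n = 3), never nuclei. In 5 comparisons the 2 classes of the same mice were fitted with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr, the quasi-likelihood test, mouse as a block and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05 and a log2 fold change of at least 1 in either direction. Standard errors were derived from the fold change and the F statistic. For Scn8a itself the threshold was the adjusted p alone. The block is part of the design because both sums come from one animal. After removal of class means, the 2 sums of a mouse correlated at 0.367, 0.075 and 0.351 for neurons against glia in mice 1, 2 and 3, and at 0.305 or more in the other 4 comparisons, across genes, which are not independent. Clusters are defined by expression, so the total number of called genes is context and not a finding. Members of the tested lists did not take part in clustering.

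The 13 lists, fixed before the data were examined, were sodium channel alpha subunits (10 genes), sodium channel beta subunits and partners (13), potassium channels (44), calcium and HCN channels (19), ionotropic glutamate receptors (17), GABA-A receptors (14), epileptic encephalopathy genes (52), activity-regulated genes (30), seizure-related granule cell genes (20), reactive astrocyte genes (24), activated microglia genes (28), stress and RNA quality genes (15) and sex check genes (6). Of the epileptic encephalopathy list, 27 members stand in other lists and 1, Cux2, among the cell type markers. Chi3l1 and Clec7a have no entry under these symbols. The rule for named genes, fixed at the same time, took every tested sodium channel alpha subunit and, from each other channel, receptor, partner and encephalopathy list, the 3 called members with the largest positive and the 3 with the largest negative fold change that lay on one side in all 3 mice. For levels per mouse it took the 5 members with the highest mean in the class plus genes fixed by name. Some genes that the rule takes are not reported here, and counts over whole lists include them. Genes chosen after their values were seen are marked as such where they appear.

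Levels are CPM, the summed counts of a gene scaled to the total UMIs of the sum, with the mean and SD over mice that had at least 20 nuclei in the class. Intervals are exact 95% Poisson intervals for levels and exact Clopper-Pearson intervals for shares, and a count of 0 allows up to 3 counts. Both cover counting error only. Differences between single mice have no replicate check and no test; a list's median log2 ratio, with 1 CPM added to each level, was placed among 10000 random lists of the same size matched on expression.

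Each fit was tested on simulated counts with 200 changed genes, 100 of them 2-fold and 100 4-fold. Of the 100 genes changed 4-fold, 82, 95, 89, 93 and 82 passed in neurons against glia, inhibitory against glutamatergic, granule against CA pyramidal, CA3 against CA1 and OPC against oligodendrocyte, and of those changed 2-fold, 18, 76, 50, 71 and 26 did. Passing here means an adjusted p under 0.05 alone, without the fold minimum, so these are not rates of calls. Of the unchanged genes 4, 9, 9, 6 and 6 passed, and 4, 2, 5, 2 and 6 were called. Far fewer genes were changed in the simulation than were called in the data. The alternatives were DESeq2 1.42.0 size factors, its Wald test, no filter on low counts, no replicate block, each mouse left out, doublets kept, at least 1000 genes per nucleus, each library clustered alone, list genes kept for clustering, nuclei thinned to 1000 UMIs, granule-like nuclei left out and no fold minimum. Leaving out 2 smaller CA3-like clusters was added after seeing the data.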

Results

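Nuclear RNA was profiled in the hippocampus of 3 adult female Scn8aD/+ mice after seizure onset, a model of developmental and epileptic encephalopathy. All 3 form 1 group and no control animals were analysed here, so the comparisons lie between classes of nuclei within the same mice. The libraries held 8863, 13904 and 4659 barcodes and 100230288, 50931257 and 140527761 UMIs for mice 1, 2 and 3. The median depth was 8859, 1711 and 25775 UMIs per barcode. After filtering, 7889, 11757 and 4393 nuclei remained. Xist, the RNA of the inactive X chromosome, was at 1462, 1340 and 1096 CPM (UMI counts scaled to the total of a library or class), and none of the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d exceeded 0.071 CPM in any library, as the labelled female sex requires.

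Glutamatergic neuron-like nuclei were 46.8% ± 26.0 of kept nuclei (SD, n = 3) and inhibitory neuron-like nuclei 8.66% ± 3.17. Granule-like nuclei of the dentate gyrus were 18.4% ± 14.6, CA1-like 8.26% ± 5.53 and CA3-like 6.76% ± 1.10. Among glia, oligodendrocyte-like nuclei were 15.1% ± 5.07, microglia-like 8.40% ± 4.42, oligodendrocyte precursor (OPC)-like 2.95% ± 0.227 and astrocyte-like 1.27% ± 1.23 (0.564% without mouse 3). Granule-like nuclei were 22.9%, 2.08% and 30.2% in mice 1, 2 and 3. Clusters left unnamed held 3.80%, 41.1% and 0.205% of the nuclei of mice 1, 2 and 3, and nuclei had been sorted, so sorting, depth and naming can set these shares. Of 54 clusters, 27 drew at least 80% of their nuclei from 1 mouse. Granule-, CA1- and microglia-like nuclei of each mouse lay mostly in clusters of their own, while most astrocyte-like nuclei of mice 1 and 3 (36 of 42 and 111 of 118) shared 1 cluster.

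Scn8a (ENSMUSG00000023033, mm10 chromosome 15, 100869858 to 101045938, plus strand) was highest in CA pyramidal-like nuclei among classes with at least 20 nuclei in 2 or more mice. Its level was 506 ± 52.6 CPM in CA2-like (SD, n = 2), 459 ± 9.93 in CA1-like, 403 ± 40.3 in CA3-like, 383 ± 23.0 in granule-like and 382 ± 24.6 CPM in subicular or cortical glutamatergic-like nuclei (n = 3 each). Among inhibitory classes, Pvalb-like nuclei held 322 ± 6.37 CPM, Sst-like 229 ± 14.3 and Lamp5-like 209 ± 32.9 (n = 2 each, mouse 2 having fewer than 20 nuclei). OPC-like nuclei held 241 ± 50.6, astrocyte-like 175 ± 86.1, microglia-like 144 ± 91.8 and oligodendrocyte-like 123 ± 74.9 CPM (n = 3). Without mouse 2 the means of the last 2 were 92.3 and 80.1 CPM. Oligodendrocyte-like nuclei held 73.8, 209 and 86.4 CPM in mice 1, 2 and 3, and markers of glutamatergic neurons in the same nuclei stood at 26.2%, 70.1% and 25.2% of their level in neuron-like nuclei.

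**Figure D1:**
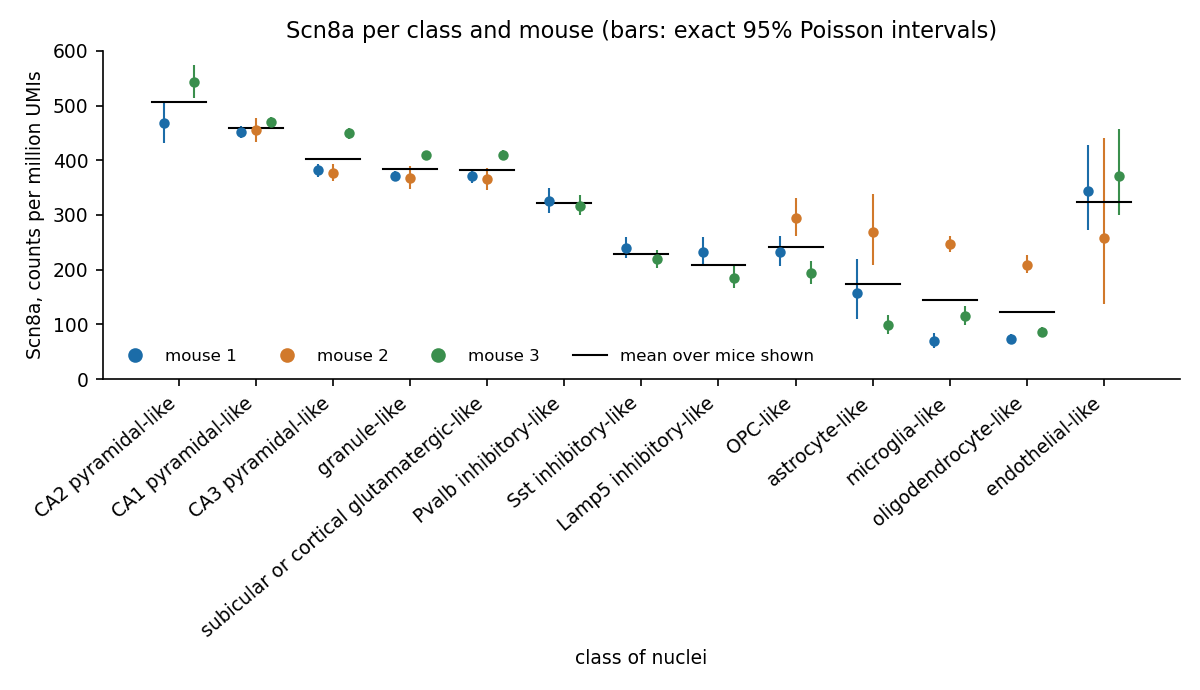
Scn8a level in CPM (vertical axis) for each class of nuclei (horizontal axis), with a point per mouse, exact 95% Poisson intervals and the mean over the mice shown as a line. CA1-like nuclei lie between 452 and 470 CPM, while oligodendrocyte-like nuclei lie at 73.8 and 86.4 CPM in mice 1 and 3 and at 209 CPM in mouse 2.

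Neuron-like against glia-like nuclei asked where the mutated channel and the genes around it are transcribed. Scn8a was higher in neuron-like nuclei, at 383 ± 26.0 against 151 ± 76.5 CPM (SD, n = 3), with a log2 fold change of 1.85 ± 0.423 (SE; adjusted p = 0.0416; higher in 3 of 3 mice). The fitted fold change includes TMM scaling and is not the ratio of these means. Of 7 tested sodium channel alpha subunits, 5 were called, all higher in neuron-like nuclei (6 when adjusted over the list alone). Scn1a differed by 1.81 ± 0.341, Scn2a by 1.58 ± 0.386, Scn9a by 2.45 ± 0.455 and Scn7a by 2.45 ± 0.444, the last at only 4.09 ± 0.640 CPM in neuron-like nuclei. Scn3a (1.20 ± 0.310, adjusted p = 0.0503) was not called.

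Other ion channels differed as well. Of 42 tested potassium channel genes 15 were called, 13 higher and 2 lower (30 when adjusted over the list alone). Kcnc2, a fast delayed rectifier, was higher by 2.32 ± 0.403, Kcnh1 by 2.52 ± 0.572 and Kcnb2 by 2.20 ± 0.533, while the axonal subunit Kcna1 (-1.49 ± 0.286) and Kcna6 (-1.90 ± 0.296) were higher in glia-like nuclei. Of 18 calcium and HCN channels 10 were higher (16 over the list alone), among them Cacna1b by 2.19 ± 0.515. Of 12 sodium channel partners 3 were higher (5 over the list alone), with the axonal scaffold gene Sptbn4 at 2.15 ± 0.523. Glutamate receptors had 5 of 17 called (11 over the list alone), with Grin1 higher by 2.34 ± 0.585 and Grin2c lower at -4.79 ± 0.749, and GABA-A receptors 7 of 12 (11 over the list alone), with Gabra5 higher by 2.18 ± 0.540. Of the 52 encephalopathy genes 23 were called, 22 higher and 1 lower (35 over the list alone); the citrate transporter gene Slc13a5 was lower, at -3.76 ± 0.335.

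Activated microglia genes had 14 of 19 called, all higher in glia-like nuclei (15 over the list alone), and reactive astrocyte genes 7 of 18, likewise (8). Activity-regulated genes had 4 of 30 called (5 over the list alone), seizure-related granule genes 2 of 19 (1), stress and RNA quality genes 2 of 15 (2) and sex check genes 0 of 2 (0, and 0 at any fold). In all, 3825 of 17207 genes were called, 1371 higher and 2454 lower. Without mouse 1, 373 genes were called, without mouse 2, 6318, and without mouse 3, edgeR called 0 (4854 at an unadjusted p under 0.05; DESeq2 called 2938). All 22 called named genes, and Scn8a, lost their call without mouse 1 and without mouse 3, and Scn8a then had an adjusted p of 0.205 and 0.181 (range over its alternatives 3.65e-05 to 0.205). With each library clustered alone 7 of the 22 stayed called, and without the mouse block 20, Kcnh1 not among them.

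Inhibitory against glutamatergic neuron-like nuclei addressed how the channel divides between these neuron types. Scn8a was lower in inhibitory neuron-like nuclei, at 264 ± 18.6 against 404 ± 22.1 CPM (SD, n = 3), a log2 fold change of -0.75 ± 0.119 (SE; adjusted p = 0.00988; lower in 3 of 3 mice). Scn9a was higher by 1.90 ± 0.115 (adjusted p = 0.000952). Scn1a was higher by 0.65 ± 0.119 (adjusted p = 0.0152), under the fold minimum. Scn2a (-0.42 ± 0.135), Scn3a (-0.26 ± 0.114) and Scn7a (-0.19 ± 0.298) did not pass. In all, 2 of 7 tested alpha subunits were called, both higher in inhibitory neuron-like nuclei (2 over the list alone). Scn8a, under the fold minimum, was not among them.

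Among 43 potassium channels 16 were called, 7 higher and 9 lower (16 over the list alone). Kcnip1 was higher by 3.80 ± 0.325 and Kcnc2 by 2.82 ± 0.348, while Kcnip3 (-2.50 ± 0.364) and Kcna4 (-1.95 ± 0.217) were lower. The sodium channel partner Fgf13 was higher by 2.60 ± 0.194, among 2 of 13 partners called (2 over the list alone). Of 19 calcium and HCN channels 5 were called (5 over the list alone), with Cacna2d2 at 2.59 ± 0.287 and Cacna1e at -2.04 ± 0.310. Kainate receptor gene Grik1 was higher by 4.59 ± 0.354 and NMDA receptor gene Grin2d by 3.01 ± 0.276, whereas Grik4 was lower at -2.02 ± 0.221, among 8 of 16 glutamate receptors (8 over the list alone). GABA-A receptors had 7 of 12 called (7 over the list alone), with Gabrg3 at 1.88 ± 0.173 and Gabra5 at -1.89 ± 0.255. Of 51 encephalopathy genes 12 were called (12 over the list alone), with Cux2 at 2.83 ± 0.159. Activity-regulated genes had 10 of 30 called, 1 higher and 9 lower (11 over the list alone). In all, 2449 of 16111 genes were called, 1278 higher and 1171 lower. The count was 1414 without mouse 1 and 1307 without the mouse block, where the adjusted p of Scn8a was 0.0646 and 0.106 (range over its alternatives 2.95e-05 to 0.106). Of 26 called named genes 24 stayed called without mouse 1, 24 without mouse 3 and 22 without the block, and 21 of the 24 still tested with nuclei thinned to 1000 UMIs.

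Granule-like against CA pyramidal-like nuclei compared the dentate gyrus with the CA fields. Scn8a did not differ detectably, at 383 ± 23.0 against 432 ± 30.7 CPM (SD, n = 3; log2 fold change -0.13 ± 0.130, adjusted p = 0.507). Other subunits did. Scn1a was lower in granule-like nuclei by a log2 fold change of -1.35 ± 0.147 (adjusted p = 0.000804), Scn7a was lower at -1.82 ± 0.413 and Scn3a was higher by 1.31 ± 0.152, so that 3 of 7 alpha subunits were called (3 over the list alone). Scn2a (0.30 ± 0.144) and Scn9a (-0.37 ± 0.484) were not.

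Other channels differed in both directions. Of 42 potassium channels 19 were called, 7 higher in granule-like nuclei and 12 lower (19 over the list alone). Kcnq5, an M-current channel, was lower at -4.82 ± 0.162, Kcnc2 at -3.41 ± 0.165 and Kcnn2, a calcium-activated channel, at -3.18 ± 0.177, while Kcnc4 was higher by 3.04 ± 0.288 and Kcnk1 by 2.15 ± 0.128. All 5 called calcium and HCN channels of 18 were lower (5 over the list alone), with Cacna1i at -3.47 ± 0.229 and Cacna2d3 at -1.80 ± 0.168. Kainate receptor genes Grik3 (2.90 ± 0.266) and Grik2 (1.56 ± 0.141) were higher, among 4 of 16 glutamate receptors (4 over the list alone). Of 12 GABA-A receptors 7 were called (7 over the list alone), with Gabrb2 at 1.44 ± 0.134 and Gabra3 at -3.60 ± 0.245. Sodium channel partners had 2 of 12 called (2 over the list alone), Fgf13 at 1.57 ± 0.215 and Fgf11 at -1.60 ± 0.216. Of 50 encephalopathy genes 9 were called (9 over the list alone), with Mef2c at 3.56 ± 0.315 and Kcnt1 at -2.94 ± 0.229. Activity-regulated genes had 8 of 30 called, all higher (8 over the list alone). Seizure-related granule genes had 11 of 19 called, 7 higher and 4 lower (12 over the list alone). Both tested sex check genes were higher (2 over the list alone), Xist by 1.32 ± 0.138. In all, 3071 of 16327 genes were called, 988 higher and 2083 lower, and 1852 without the mouse block. Of 25 called named genes 19 stayed called without the block, Fgf13 and Fgf11 not among them, and 21 without mouse 2, Scn7a not among them; Scn9a changed sign without mouse 3 (0.44).

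CA3-like against CA1-like nuclei compared the pyramidal fields. Scn8a did not differ detectably, at 403 ± 40.3 against 459 ± 9.93 CPM (SD, n = 3; log2 fold change -0.23 ± 0.110, adjusted p = 0.218). All 3 CA1-like clusters had the astrocyte marker Gpc5 and no fixed CA1 marker among their 10 leading genes. A CA3-like cluster of 153, 11 and 79 nuclei in mice 1, 2 and 3 had the mossy cell marker Calcrl among its leading genes, beside the CA3 marker Tspan18. It is among the 2 smaller CA3-like clusters that an alternative leaves out. Scn7a was higher in CA3-like nuclei by 2.43 ± 0.349 (adjusted p = 0.00477), at 12.6 ± 1.80 CPM. Of 7 alpha subunits 2 were called (2 over the list alone), and Scn1a (-0.08 ± 0.106), Scn2a (0.23 ± 0.153), Scn3a (-0.16 ± 0.114) and Scn9a (-0.52 ± 0.217) were not.

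Kcnq5 was higher in CA3-like nuclei by 2.21 ± 0.123 and Kcnc1 by 1.54 ± 0.124, while Kcnh7 was lower at -4.43 ± 0.394, among 10 of 42 potassium channels, 5 in each direction (10 over the list alone). The L-type channel Cacna1c was higher by 1.502 ± 0.119 and Cacna2d2 lower at -2.34 ± 0.258, with 3 of 18 calcium and HCN channels called (3 over the list alone). Grik4, a kainate receptor subunit, was higher by 2.42 ± 0.263, and 4 of 16 glutamate receptors were called (4 over the list alone). All 3 called GABA-A receptors of 12 were lower (3 over the list alone), with Gabra3 at -1.67 ± 0.117. Encephalopathy genes had 4 of 50 called (4 over the list alone), with Pcdh19 at -1.12 ± 0.172. None of the 12 tested sodium channel partners was called by edgeR, 4 of them passing without the fold minimum (0 over the list alone). In all, 1562 of 15040 genes were called, 1011 higher and 551 lower, and 440 without the mouse block. Of 19 called named genes 7 stayed called without the block, Scn7a, Kcnc1, Cacna1c and Pcdh19 not among them, 13 without mouse 1, and 10 of the 13 still tested with nuclei thinned to 1000 UMIs. Pcdh19 also lost its call without mouse 2, and without mouse 3 Scn1a (0.02) and Scn2a (-0.003) changed sign.

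OPC-like against oligodendrocyte-like nuclei compared precursors with mature cells of that lineage. Scn8a was at 241 ± 50.6 against 123 ± 74.9 CPM (SD, n = 3), a log2 fold change of 1.07 ± 0.280 that missed the threshold (adjusted p = 0.0531; range over its alternatives 0.00932 to 0.266; higher in 3 of 3 mice). Scn3a was higher in OPC-like nuclei by 1.97 ± 0.416 and Scn1a by 1.38 ± 0.342, so 2 of 5 alpha subunits were called (3 over the list alone). Scn2a (0.87 ± 0.263) and Scn9a (0.29 ± 0.459) were not. In these OPC-like nuclei the glutamatergic markers stood at 20.2%, 64.1% and 19.7% of their level in neuron-like nuclei.

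The adhesion gene Nrcam was higher by 2.20 ± 0.528 and its paranodal relative Nfasc lower at -1.56 ± 0.330, the 2 called of 12 partners (5 over the list alone). Of 40 potassium channels 9 were called, 6 higher and 3 lower (14 over the list alone), with Kcnk2 at 3.83 ± 0.752, Kcnh5 at 3.36 ± 0.567 and Kcna1 at -2.64 ± 0.339. Grin3a was higher by 4.25 ± 0.584 and Grid1 by 2.84 ± 0.518, among 4 of 16 glutamate receptors, all higher (9 over the list alone). Calcium and HCN channels had 4 of 17 called (7 over the list alone), with Hcn2 at -2.30 ± 0.449, and GABA-A receptors 3 of 11, all higher (3 over the list alone), with Gabra3 at 2.43 ± 0.353. Encephalopathy genes had 7 of 51 called (11 over the list alone), with Gnao1 at -1.73 ± 0.327. In all, 2005 of 12519 genes were called, 1043 higher and 962 lower. The count was 1247 without mouse 1, 3159 without mouse 2, and 0 by edgeR without mouse 3 (2541 at an unadjusted p under 0.05; 840 by DESeq2), so every call among the 22 named genes was lost without mouse 3. Without mouse 1, 11 of them remained called, Scn1a, Nrcam, Nfasc and Gnao1 not among them. Without the mouse block 15 remained called and with each library clustered alone 11, Scn1a, Nrcam and Nfasc in neither.

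**Figure D2:**
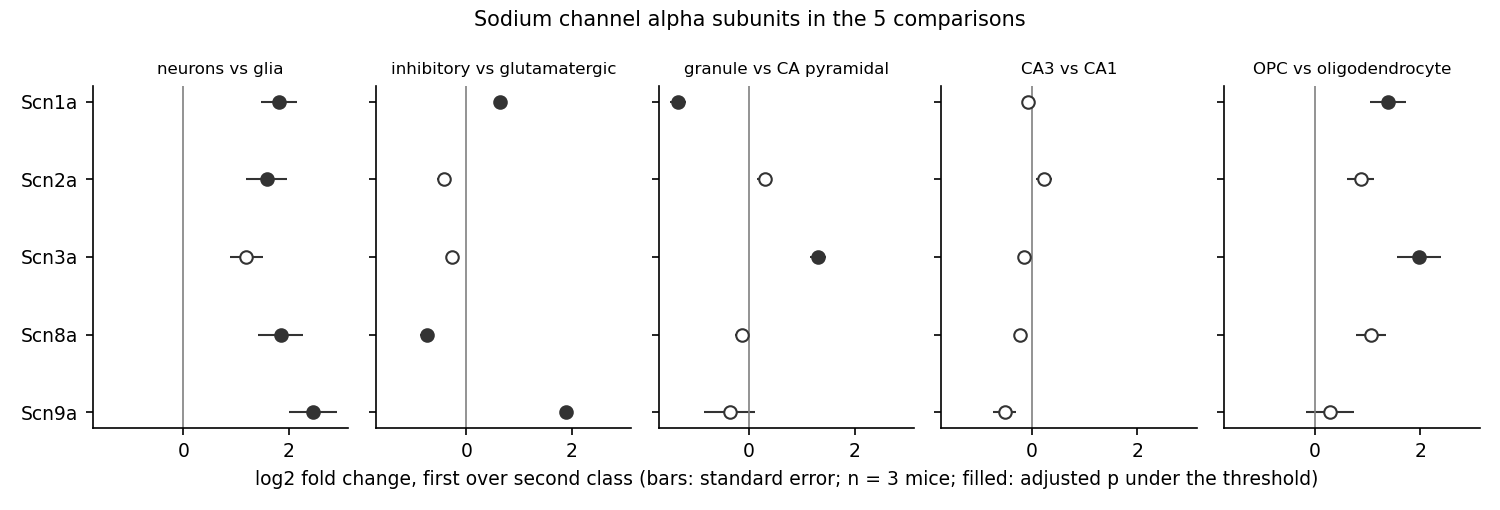
Fitted log2 fold change (horizontal axis, first over second class) of 5 sodium channel alpha subunits (vertical axis) in the 5 comparisons, with standard errors over 3 mice and filled points where the adjusted p passed the threshold. Scn8a lies at 1.85 for neuron-like against glia-like nuclei and at -0.75 for inhibitory against glutamatergic neuron-like nuclei.

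Between the 3 mice, activity-regulated genes of granule-like nuclei differed in level. These are values of single mice, from different clusters in each, with no test. They rest on 1806, 244 and 1328 granule-like and 886, 221 and 512 CA1-like nuclei of mice 1, 2 and 3. Nr4a2, an immediate early transcription factor, was at 758, 28.2 and 138 CPM in mice 1, 2 and 3, Nr4a1 at 435, 33.8 and 164 CPM, Nr4a3 at 507, 19.3 and 200.2 CPM, Fos at 55.3, 3.38 and 30.5 CPM and Arc at 136, 26.7 and 58.3 CPM. The median log2 ratio of the 30 genes was 2.38 for mouse 1 over mouse 2, with 29 higher, above all 10000 random lists (percentile 100.0). For mouse 3 it was 1.33 over mouse 2 (28 higher, percentile 100.0) and -1.06 over mouse 1 (6 higher, percentile 0.0). Stress and RNA quality genes in the same nuclei had a median of 0.82 for mouse 1 over mouse 2 (percentile 100.0). The growth factor gene Bdnf was at 743, 664 and 1472 CPM and Homer1 at 1199, 916 and 1256 CPM. In CA1-like nuclei Bdnf was at 141, 87.5 and 841 CPM, Inhba at 24.4, 92.5 and 424 CPM and Nptx2 at 134, 56.5 and 356 CPM, while Nr4a1 was at 298, 46.2 and 186 CPM. The list's median log2 ratio there was 1.46 for mouse 1 over mouse 2 (27 of 30 higher), 1.78 for mouse 3 over mouse 2 (29 higher) and 0.31 for mouse 3 over mouse 1 (16 higher), where random lists had a median of -0.32 (percentile 100.0 in each).

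Several seizure-related granule cell genes were highest in mouse 3. Sorcs3 was at 286, 798 and 4171 CPM in granule-like nuclei of mice 1, 2 and 3, the opioid peptide gene Penk at 126, 44.8 and 289 CPM and the proteoglycan gene Acan at 3.10, 7.06 and 252 CPM. Neuropeptide gene Npy was at 11.5, 25.2 and 25.4 CPM and Calb1 at 46.6, 58.9 and 68.8 CPM. The list's median log2 ratio was 0.38 for mouse 3 over mouse 1, where random lists had a median of -0.40 (percentile 100.0). The list was mixed there, with 12 of 20 genes higher, 5 genes more than 2-fold higher and 5 more than 2-fold lower. For mouse 1 over mouse 2 the median was 0.14 (percentile 52.4).

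**Figure D3:**
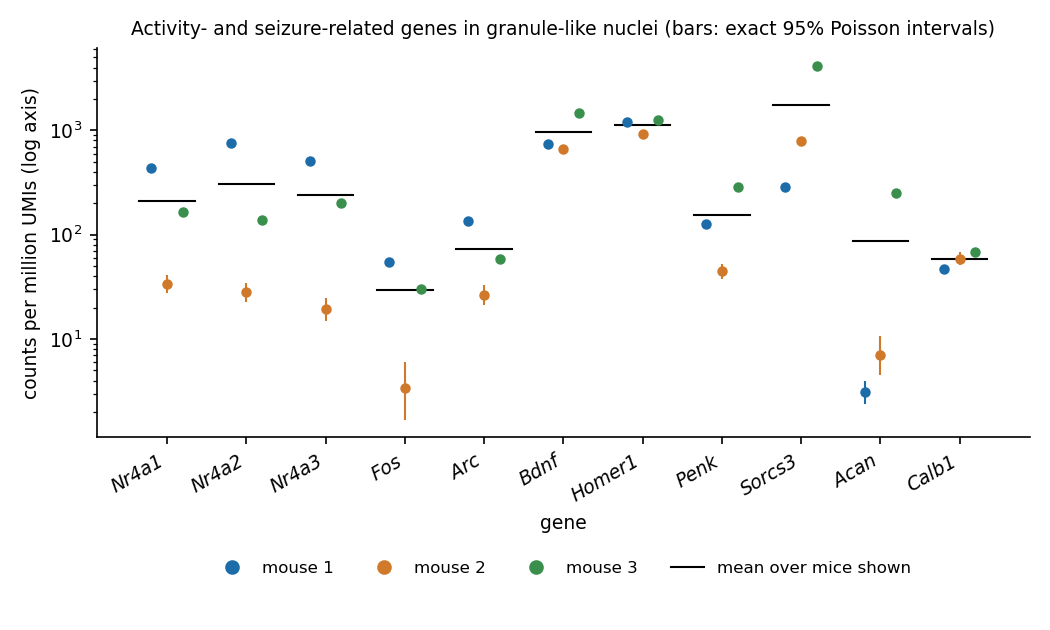
Levels in granule-like nuclei (vertical axis, CPM, log axis) of activity-regulated and seizure-related genes (horizontal axis), with a point per mouse, exact 95% Poisson intervals and the mean as a line. Nr4a2 lies at 758, 28.2 and 138 CPM in mice 1, 2 and 3.

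Reactive astrocyte genes were highest in the astrocyte-like nuclei of mouse 3, where 118 nuclei were compared with 42 and 70 in mice 1 and 2. Glutamatergic markers in these nuclei stood at 28.1%, 76.1% and 22.4% of their level in neuron-like nuclei of mice 1, 2 and 3. Filament genes Gfap and Vim were at 287, 618 and 2056 CPM and at 27.0, 225 and 791 CPM, Serpina3n at 13.5, 46.6 and 318 CPM, Cd44 at 8.98, 27.2 and 692 CPM and the metallothionein gene Mt1 at 759, 656 and 1282 CPM. All 17 measured members were higher in mouse 3 than in mouse 1, with a median log2 ratio of 2.83 (percentile 100.0). In microglia-like nuclei complement gene C1qb was at 306, 104 and 362 CPM, Ctsd at 304, 109 and 154 CPM, Apoe at 80.7, 54.8 and 94.5 CPM, Trem2 at 131, 31.5 and 49.2 CPM and Cd68 at 37.2, 10.2 and 5.25 CPM. The median log2 ratio of 23 activated microglia genes was 1.73 for mouse 1 over mouse 2 and -0.42 for mouse 3 over mouse 1. For mouse 3 over mouse 2 it was 1.03, with 19 of 23 higher, though Cd68 was lowest in mouse 3. Glutamatergic markers in these nuclei stood at 31.0%, 74.2% and 36.7% of their level in neuron-like nuclei, highest in mouse 2. Whether neuronal RNA accounts for the lower list median of mouse 2 was not tested. The coefficient of variation between mice is the square root of edgeR's common dispersion over the genes that pass the count filter in a class. It was 24.8% in subicular or cortical glutamatergic-like and 42.1% in microglia-like nuclei, and 26.4% and 29.2% without mouse 2.

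**Figure D4:**
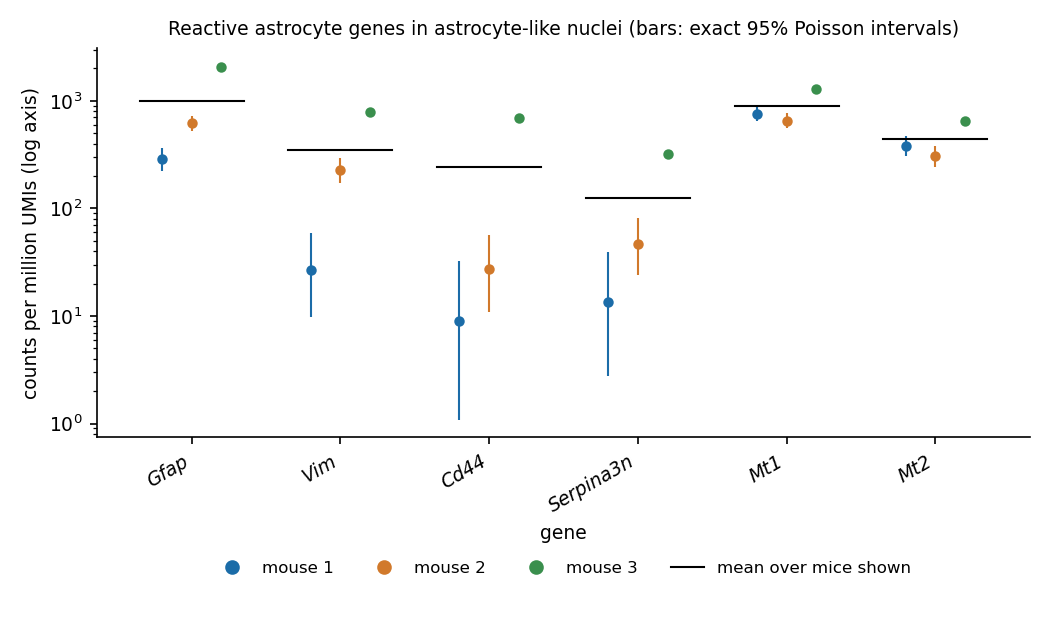
Levels in astrocyte-like nuclei (vertical axis, CPM, log axis) of 6 reactive astrocyte genes (horizontal axis), with a point per mouse, exact 95% Poisson intervals and the mean as a line. Gfap lies at 287, 618 and 2056 CPM in mice 1, 2 and 3.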

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

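Of the tests below, those on Cajal-Retzius-like, astrocyte-like, oligodendrocyte-like and microglia-like nuclei were chosen after the result was seen. For the others the Scn8a levels had been seen and the marker levels that decide them had not.

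Among classes with at least 20 nuclei in 2 or more mice, Scn8a was counted in 3 kinds of nuclei that no comparison used. It was at 204.9 CPM in Cajal-Retzius-like nuclei (SD 50.5, n = 3), at 324 CPM in endothelial-like nuclei (SD 59.2, n = 3) and at 339 CPM in unnamed nuclei (SD 25.9, n = 2, mice 1 and 2). Immature neuron-like, mural-like and fibroblast-like nuclei, also in no comparison, had at least 20 nuclei in only 1 mouse each. Scn8a was there at 576, 396 and 45.1 CPM. Whether any of these nuclei transcribe Scn8a is left open.

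Scn8a in non-neuronal nuclei may be RNA of neurons, carried as free RNA or in doublets, so its level was set against that of 8 glutamatergic markers, each as a percent of the level in neuron-like nuclei of the same mouse. In endothelial-like nuclei the markers stood at 102%, 85.7% and 84.8% of the neuron-like level in mice 1, 2 and 3, and the Scn8a percent was 0.890 times the marker percent in mouse 1 and 1.07 times in mouse 3, which neuronal RNA would give. In Cajal-Retzius-like nuclei the ratio was 1.30, 0.883 and 1.44, each with 1 inside its 95% bounds. That class is itself one of neurons, so the ratio cannot tell its own RNA from that of other neurons. In oligodendrocyte-like and microglia-like nuclei of mouse 2 the higher of both ratios was 0.922. In mice 1 and 3 it was 0.746 and 0.834 in oligodendrocyte-like and 0.596 and 0.760 in microglia-like nuclei. Astrocyte-like nuclei had 1.48, 0.978 and 1.07 in mice 1, 2 and 3, each with 1 inside its 95% bounds. The upper 95% bound was under 1 in oligodendrocyte-like nuclei of mice 1, 2 and 3 (0.86, 0.924 and 0.979). It was also under 1 in microglia-like nuclei of mice 1 and 3 (0.77 and 0.947). The markers thus overstate the Scn8a that neuronal RNA brings there, and a ratio of 1 is not an exact yardstick. Within that limit, neuronal RNA could account for the levels of these 3 glial classes in every mouse. In OPC-like nuclei the ratio was 3.05 in mouse 1 and 2.40 in mouse 3 (95% bounds 1.97 to 2.93), more than glutamatergic RNA alone would bring. In mouse 2 it was 1.28, with 95% bounds of 1.065 to 1.524. These lie above 1, but the lower one is under the 1.5 that this test asked of mice 1 and 3. Neuronal RNA therefore stays open in mouse 2. No biological explanation was tested, since the design has a single group.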

How the results depend on the processing

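The alternative that leaves out 2 smaller CA3-like clusters was chosen after seeing the data; the others were fixed before. Of 1606 values of named genes under an alternative, 1385 kept their direction and side of the threshold, 208 lost a call, 6 gained one and 7 reversed. The library of mouse 2 was shallow and carried the most neuronal RNA in glia-like nuclei, and mouse and batch coincide, which limits all comparisons of mice. Its few granule-like and CA1-like nuclei were not shallow, with medians of 13143 and 16983 UMIs against 10135.5 and 14085 in mouse 1. They may not represent a library in which 41.1% of nuclei stayed unnamed. Where a value below differs, the cause was not tested, except that thinning and leaving out a mouse leave fewer counts. Without a filter on low counts the median log2 fold change of all genes was 0.193 for neurons against glia, -0.111 for inhibitory against glutamatergic and -0.13 for granule against CA pyramidal, so changes there are relative to it.

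Leaving out 1 mouse at a time gave 0 to 6318 called genes for neurons against glia, 1414 to 2768 for inhibitory against glutamatergic and 0 to 3159 for OPC against oligodendrocyte. For neurons against glia 0 were called by edgeR without mouse 3, with 4854 at an unadjusted p under 0.05 and 2938 by DESeq2, and for OPC against oligodendrocyte 0, 2541 and 840. Called alpha subunits ranged from 0 to 6, 1 to 2 and 0 to 4 in these 3, and from 1 to 2 in CA3 against CA1. Scn8a ranged from 1.497 to 2.38 for neurons against glia (adjusted p 0.205 without mouse 1, 0.181 without mouse 3), from -0.83 to -0.66 for inhibitory against glutamatergic and from 0.83 to 1.38 for OPC against oligodendrocyte. Of genes that reversed, Scn7a ranged from -0.56 to 0.14 (inhibitory against glutamatergic), Scn9a from -0.82 to 0.44 (granule against CA pyramidal) and from -0.007 to 0.27 (OPC against oligodendrocyte), and in CA3 against CA1 Scn1a from -0.16 to 0.02 and Scn2a from -0.003 to 0.33. The coefficient of variation between mice ranged from 22.6% to 40.6% in CA1-like, 20.9% to 37.3% in CA3-like and 21.6% to 39.8% in all CA pyramidal-like nuclei.

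Without the replicate block, 1307 genes were called for inhibitory against glutamatergic, 1852 for granule against CA pyramidal and 440 for CA3 against CA1, and 1, 0 and 1 alpha subunits for inhibitory against glutamatergic, CA3 against CA1 and OPC against oligodendrocyte. Scn8a for inhibitory against glutamatergic was then -0.77 (adjusted p = 0.106). The block changed no other call of Scn8a. Without it 3715 and 1569 genes were called for neurons against glia and OPC against oligodendrocyte.

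Thinning each nucleus to 1000 UMIs gave 2330, 929, 1231, 541 and 1165 called genes in neurons against glia, inhibitory against glutamatergic, granule against CA pyramidal, CA3 against CA1 and OPC against oligodendrocyte, and 3, 1 and 0 alpha subunits in neurons against glia, inhibitory against glutamatergic and CA3 against CA1. Scn8a for inhibitory against glutamatergic was then -0.58 (adjusted p = 0.0837). Its level was 444 CPM in CA2-like, 362 in Pvalb-like and 287 in all inhibitory neuron-like nuclei. With each library clustered alone, 2429 genes and 3 alpha subunits were called for neurons against glia, with Scn8a at 1.86 (adjusted p = 0.0598), 1 alpha subunit each in inhibitory against glutamatergic, CA3 against CA1 and OPC against oligodendrocyte, and Grik3 reversed at -0.15 in CA3 against CA1. Scn8a in Pvalb-like nuclei was 331 CPM. Shares were then 1.64% for CA2-like, 5.01% for CA3-like, 0.365% for Cajal-Retzius-like, 0.789% for endothelial-like, 0.065% for immature neuron-like and 0.473% for mural-like nuclei.

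With DESeq2's Wald test 5878 genes were called for neurons against glia. With no fold minimum 4252 were called for inhibitory against glutamatergic, with 4 alpha subunits, and 2809 for CA3 against CA1. Scn8a in OPC against oligodendrocyte passed the threshold with DESeq2 size factors (1.08, adjusted p = 0.0462), with its Wald test (1.04, 0.0273), with no filter on low counts (1.00, 0.0183), without mouse 2 (1.38, 0.00932), with at least 1000 genes per nucleus (1.08, 0.0482) and with list genes kept for clustering (1.09, 0.049). At least 1000 genes per nucleus also gave 1 alpha subunit for inhibitory against glutamatergic and shares of 8.64% for CA3-like, 0.409% for Cajal-Retzius-like and 1.77% for Lamp5-like nuclei. Keeping doublets gave 1 alpha subunit in CA3 against CA1 and in OPC against oligodendrocyte, shares of 1.89% for Lamp5-like and 3.35% for OPC-like nuclei, and Scn8a at 243 CPM in Lamp5-like and 368 CPM in unnamed nuclei. Keeping list genes for clustering gave 0.559% endothelial-like and 0.117% immature neuron-like nuclei. Leaving out granule-like nuclei reversed Scn3a in inhibitory against glutamatergic (0.11), and leaving out the 2 smaller CA3-like clusters gave 1 alpha subunit in CA3 against CA1.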

Other observations

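The alternative splits of the samples were counted after the results were seen. The other tests below were written before the marker levels they use were seen.

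Mean sodium channel levels varied between inhibitory classes in mice 1 and 3 (n = 2, SD), with wide spreads. Scn1a was at 456 ± 66.8 CPM in Pvalb-like, 445 ± 72.9 in Lamp5-like and 261 ± 100.1 in Sst-like nuclei, against 98.6 ± 19.5 in granule-like nuclei (n = 3). Scn9a was at 82.0 ± 42.9 CPM in Pvalb-like, 41.2 ± 17.1 in Sst-like and 26.1 ± 26.2 in Lamp5-like nuclei. Scn3a was at 34.7 ± 10.3 in Pvalb-like, 85.15 ± 17.44 in Sst-like and 101 ± 39.4 CPM in Lamp5-like nuclei. These differences were not tested.

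Several further genes were chosen after their values were seen. In microglia-like nuclei the proliferation genes Mki67 and Top2a were at 1.28, 3.64 and 141 CPM and at 0.640, 2.18 and 180 CPM in mice 1, 2 and 3, and 42 nuclei of mouse 3 formed a microglia-like cluster of their own. Fosb in granule-like nuclei was at 142, 7.98 and 26.8 CPM, Inhba at 72.2, 99.5 and 227 CPM, and Penk in CA1-like nuclei at 9.76, 7.20 and 134 CPM. Hspb1 in astrocyte-like nuclei was at 194 CPM in mouse 3 and had 0 counts in mice 1 and 2, which allow up to 13.5 and 11.7 CPM.

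Activity-regulated genes were lower in granule-like nuclei of mouse 2 than of mouse 1, which might reflect dilution by RNA of other cells. The granule markers would then fall by as much. Their median log2 ratio of mouse 1 to mouse 2 was 0.19 (bootstrap 95% interval -0.157 to 0.807), against 2.38 (1.84 to 2.73) for the activity-regulated genes. A fall of that size was thus not seen in the nuclei named granule-like. The same markers served to name the clusters, so nuclei diluted enough to lose them would stay out of the class, which limits this test. Stress and RNA quality genes stood higher in mouse 1 by a median of 0.82, and handling, batch and animal cannot be told apart, since each mouse is a batch. No biological explanation was tested.

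Reactive astrocyte genes were higher in astrocyte-like nuclei of mouse 3 than of mouse 1. RNA of fibroblast-like or mural-like cells could bring Vim. The rise of Vim would need 225% of the fibroblast-like level (Vim at 340 CPM in fibroblast-like nuclei), which no share of fibroblast-like RNA can reach. The Vim levels alone fix this outcome, for Vim only, so the fibroblast and mural markers, at 2.29% of the fibroblast-like level, did not decide it. Vim of mural-like nuclei was not used as a reference, so mural-like RNA was not tested. Dilution by neuronal RNA in mouse 1 would raise the astrocyte markers as well, and their median log2 ratio was -0.116 (bootstrap 95% interval -0.290 to 0.699) against 2.83 (1.49 to 4.46). These markers also served to name the astrocyte-like clusters, which limits this test in the same way. Batch and animal stay open, as do the 42 astrocyte-like nuclei of mouse 1. No biological explanation was tested.

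For each of the 5 comparisons the 6 sums can be split in 10 ways into 3 and 3, too few for a share under 0.05. Only 1 split, the real one, called as many genes. The classes were defined by expression in these same nuclei, so that outcome was set in advance and is no evidence against chance. The real splits called 3825, 2449, 3071, 1562 and 2005 genes in neurons against glia, inhibitory against glutamatergic, granule against CA pyramidal, CA3 against CA1 and OPC against oligodendrocyte. The highest of the 9 other splits called 0 in each by edgeR, with at most 839, 803, 592, 632 and 682 genes at an unadjusted p under 0.05 and at most 66, 1, 9, 1 and 23 by DESeq2. Of those 9, 3 part all 3 mice as the real split does, and the others part 1 mouse.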
